A study of Bos taurus with 12 samples.

How the data were processed

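Sperm DNA of bulls (Bos taurus) was profiled by enzymatic methylation sequencing (EM-seq), in which enzymes in place of bisulfite convert unmethylated cytosines, so that methylated cytosines are read as C and unmethylated ones as T. The labels give 12 samples in 2 groups of 6, named low BFI and high BFI. BFI is not spelled out in the labels, and the running numbers in the sample titles pair no samples. Genomic DNA was extracted with a column kit, per the labels' protocols. The submitters' processing notes name Trimmomatic, Bismark and methylKit as tools and ARS-UCD1.2 and bosTau9 as genome builds, with no versions, roles or settings. All positions below are those of the deposited table on that assembly.

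The values analysed here are the authors' own comparison of the groups. Per the file headers, the deposited table gives for each tile a p-value, a q-value and a methylation difference, and the header names are those that methylKit writes. The deposited differences run from -21.3 to 20.8 and were read as percentage points. Neither the headers nor the labels say which group was subtracted from which. The sign of a difference is therefore reported as deposited, and no group is named as the more methylated. No column belongs to a single sample (0 columns of values per sample were left unmatched). Methylation levels, read counts and coverage per sample were not used here, the depth is unknown, and no spread between bulls could be computed. Whether the authors' test allowed for differences between bulls beyond read sampling is not given in the sources used here, so the deposited p-values and q-values cannot be read as a comparison with the spread between replicates. The labels also do not say whether each sample came from a different bull.

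The table lists 7290 tiles of 500 bp whose starts lie on a grid of 100 bp, so that 5815 tiles share bases with the tile listed before them. The listed tiles make up 0.0304% of the grid positions between the first and last listed tile of each chromosome. The rule by which the authors chose them is not given in the sources used here, so shares below are shares of listed tiles and not of the genome. Each tile carries the closest annotated feature, its class of position (within, promoter, downstream or distal intergenic) and its type (CpG island, exon, coding sequence, intron or untranslated region). The promoter class is wide, with deposited distances to the closest feature of up to 9961 bp. For 399 introns the deposited start lies above the end, and the edges were swapped. Gaps in bp are from the nearest edge of the tile to the nearest edge of that feature. A gene ID accompanied 3318 tiles, 2932 tiles had a CpG island as closest feature, and 1040 tiles had an exon with a transcript ID only and no gene. The table names 540 gene IDs, 463 of them with a description. The NCBI gene numbers of 107 IDs were looked up in a RefSeq gene table of assembly ARS-UCD2.0, used for names only, and 106 matched. A further 44 descriptions were given symbols by hand, and all 44 symbols lie on the same chromosome in that table.

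As fixed in the design for a table that holds only the authors' comparison, no new test between the groups was run. A tile was counted as differentially methylated at a deposited q under 0.05 and a deposited difference of at least 10 percentage points in either direction. The share of negative differences was tested with an exact binomial test against equal shares, two-sided. Position classes, feature types and chromosomes were compared between counted and other listed tiles with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 10 classes and types and over the 27 chromosomes. At the gene level, genes with a counted tile were compared with genes with other listed tiles for 11 gene lists in the same way. Clustering was tested by permuting the counted tiles and their signs among the listed tiles of each chromosome 100000 times, with the number of pairs of one sign within 1000 bp as the statistic. Overlapping tiles are not independent, so counted tiles of one sign within 1000 bp were also merged into regions, and listed tiles within 1000 bp into loci. Blocks are runs of listed tiles with gaps of at most 50000 bp. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

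The groups, thresholds, tests, gene lists and the rule for named genes were chosen before the data were examined. By that rule the text names the 12 genes with the largest positive and the 12 with the largest negative counted tiles among genes with a symbol, the 5 genes with the most counted tiles, every counted member of a gene list with at most 8 of them or otherwise the 4 largest, and the tile with the smallest q of each sign. Leaving out genes described in the table only as an uncharacterized LOC entry (LOC784741 and LOC618600), 10 named genes had a counted tile. Genes of multicopy families and IDs with no name are given as uncertain, because reads from copies can be placed on one another. Other named genes were chosen after their values were seen, and the text says where. The gene lists were imprinted genes, germline and piRNA genes, sperm structure and fertilisation genes, DNA methylation and chromatin regulators, developmental transcription factors, Wnt signalling genes, calcium and cAMP signalling genes, neuronal adhesion and synapse genes, leukocyte markers, epithelial and accessory gland markers, and multicopy families. The lists of developmental transcription factors, Wnt signalling genes and calcium and cAMP signalling genes hold only genes that match set gene family prefixes.

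The procedures were tested on simulated data at the positions of the 7290 listed tiles. Of tiles simulated with a true change, 97.5% were recovered, and 0.0% of unchanged tiles were called. The simulated counts were binomial, independent between tiles and without spread between samples, and their p-values came from a likelihood ratio test. These 2 shares therefore do not give the error rate of the deposited q-values. Random class labels gave a p under 0.05 in 5.5% of tests and classes with planted calls in 100%. Random placements were called clustered in 7.5% of runs and planted runs of tiles in 100%. Alternatives covered the q threshold, the minimum difference, merging, the adjustment over all listed tiles, the autosomes alone and other neighbour distances. Alternatives that need coverage or values per sample were not run.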

Results

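DNA methylation of bull sperm was compared between 6 samples of the low BFI group and 6 of the high BFI group, in a series that its description places in the study of bull fertility. The authors' deposited table holds the comparison of the groups for 7290 tiles of 500 bp on 27 chromosomes. The depth behind each tile is unknown, and the table gives no error between bulls. Whether its q-values allow for differences between bulls is not given in the sources used here.

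Between the groups, 203 tiles differed by at least 10 percentage points at a q under 0.05. They formed 57 regions of 500 to 4300 bp, and 133 of the tiles were distal intergenic. The genes nearest to them included GLIS3, a zinc finger transcription factor, the cytoskeletal gene SEPTIN10, the cGMP-hydrolysing phosphodiesterase PDE5A and CXXC4, an inhibitor of Wnt signalling. The largest counted difference nearest to each of these genes was negative, from -13.9 to -10.3 percentage points. For CXXC4 that tile was distal intergenic, 57808 bp from the gene's coding sequence. The largest differences of all lay in intergenic DNA on chromosomes 16 and 1 and next to an olfactory receptor gene on chromosome 15. Most other listed tiles differed little. The median size of the difference over all listed tiles was 1.48 percentage points, and 5236 tiles had a q under 0.05 at any difference.

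GLIS3 had the largest difference among named genes outside the multicopy list. In the authors' deposited table, a tile on chromosome 8 from 40569401 to 40569900 differed by -13.9 percentage points (q = 8.63e-31), and all 5 tiles listed for GLIS3 were counted. The tile was classed as promoter and lay 4316 bp from the nearest coding sequence. SEPTIN10 carried a tile within an intron on chromosome 11, from 44299201 to 44299700, at -12.4 percentage points (q = 4.64e-25) in the authors' deposited table. PDE5A carried 3 counted tiles in an intron on chromosome 6. The largest, from 5794701 to 5795200, stood at -10.3 percentage points in the authors' deposited table (q = 5.03e-60). CA10, a member of the carbonic anhydrase family, also carried a counted tile in an intron. Its tile on chromosome 19, from 1356301 to 1356800, was listed at -10.0 percentage points in the authors' deposited table (q = 2.60e-21). GLYAT, which conjugates glycine to acyl groups, had a counted tile 278 bp beyond an exon, classed as downstream. That tile, on chromosome 15 from 82126901 to 82127400, had a difference of -11.2 percentage points in the authors' deposited table (q = 2.85e-22). In its block 17 of 22 listed tiles were negative. The block also holds a glycine-N-acyltransferase-like gene, with a tile at 7.21 percentage points. Whether reads of such related genes were placed on one another was not tested, so GLYAT carries the same uncertainty as multicopy genes.

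For the remaining genes outside the multicopy list, the counted tile with the largest difference lay 33146 to 80933 bp from the annotated feature. The nearest annotated gene was MGAT4C, of a glycosyltransferase family, for a tile on chromosome 5 from 15824101 to 15824600, with a gap of 80933 bp to its 5′ UTR. The authors' deposited table gives -12.1 percentage points there (q = 1.19e-22). For CXXC4 the tile lay at 20762601 to 20763100 on chromosome 6, with a gap of 57808 bp, and had -10.8 percentage points in the authors' deposited table (q = 2.65e-28). RNF180, an E3 ubiquitin ligase gene, was 37059 bp from a tile on chromosome 20, from 15068901 to 15069400, at -10.1 percentage points in the authors' deposited table (q = 2.58e-55). SERTM2 was 33146 bp from a tile on chromosome X, from 59755301 to 59755800, listed at -10.3 percentage points in the authors' deposited table (q = 8.43e-168). These 9 genes include 5 with a counted tile in the gene or within 5000 bp of the annotated feature.

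The olfactory receptor 4C6-like gene on chromosome 15 is of a multicopy family and is reported as uncertain. All 4 of its listed tiles were counted, and the authors' deposited table gives -20.9 percentage points (q = 3.00e-46) from 1092801 to 1093300, 1135 bp from the coding sequence. The largest negative difference in the authors' deposited table, -21.3 percentage points (q = 3.39e-69), lay on chromosome 16 from 11333301 to 11333800, with a gap of 589785 bp to the closest exon. The smallest q of a negative counted tile in the authors' deposited table, 4.78e-211, belonged to chromosome 6 from 5456501 to 5457000. That tile differed by -11.3 percentage points and lay 288053 bp from the closest CpG island.

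**Figure D1:**
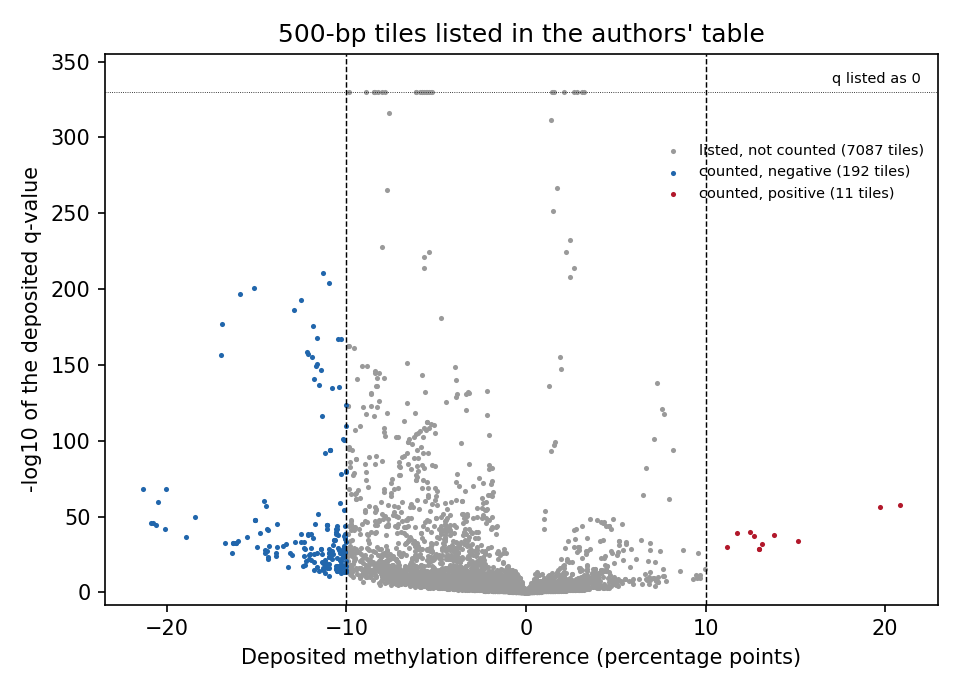
Deposited methylation difference in percentage points (horizontal axis) against -log10 of the deposited q-value (vertical axis) for the 7290 listed tiles, 1 point per tile. Blue and red points are the 192 negative and 11 positive tiles counted at a q under 0.05 and a difference of at least 10 percentage points (dashed lines), and the 27 tiles with a q listed as 0 are drawn on the dotted line.

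The sign of the counted tiles was mostly negative. Of the 203 counted tiles, 192 were negative and 11 positive, a negative share of 94.6% (95% exact interval 90.5% to 97.3%; exact binomial p = 7.57e-44, two-sided). After merging, 53 of the 57 regions were negative, or 93.0% (95% exact interval 83.0% to 98.1%; exact binomial p = 5.91e-12). The counted tiles and regions lie in 28 blocks and come from the same 12 samples, so they are not independent. These intervals and p-values do not measure the spread between samples. Negative differences also made up 70.9% of the listed tiles that were not counted. Of the 11 positive tiles, 10 lay on chromosome 1 nearest to ENSBTAG00000006648, an ID with no name in the table, reported as uncertain. The largest, from 379101 to 379600, lay 28712 bp from its coding sequence and had 20.8 percentage points and the smallest q of a positive tile (2.84e-58) in the authors' deposited table. The remaining positive tile overlapped a CpG island on chromosome 19, from 13425201 to 13425700, at 11.2 percentage points (q = 1.42e-30) in the authors' deposited table. With a minimum of 20 percentage points, 7 of 8 tiles were negative, and the exact binomial p was 0.0703.

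Counted tiles were more frequent in distal intergenic positions and less frequent downstream of the closest annotated feature, which is a gene feature or a CpG island. In distal intergenic positions 133 of 2790 listed tiles were counted (4.77%), against 70 of 4500 elsewhere (1.56%), an odds ratio of 3.17 (Fisher's exact test, adjusted p = 2.90e-14). The share was lower for tiles downstream of a feature, 21 of 1888 (odds ratio 0.323, Fisher's exact test, adjusted p = 1.12e-07), and within features, 33 of 1869 (odds ratio 0.555, adjusted p = 0.00358). By type, tiles closest to a 3′ UTR were counted more often, 27 of 223 (odds ratio 5.39, Fisher's exact test, adjusted p = 3.67e-10), and those closest to an exon less often, 26 of 1393 (odds ratio 0.615, adjusted p = 0.0371). None of the 27 overlapped a 3′ UTR. All 27 lay on chromosome X, 11011 to 36869 bp from the UTR, and without the 6 blocks with the most counted tiles, an alternative chosen after seeing the data, the odds ratio for 3′ UTRs was 0.748 (Fisher's exact test, adjusted p = 1). Promoter tiles (16 of 743), CpG islands (69 of 2932), introns (29 of 1104), coding sequence (45 of 1237) and 5′ UTRs (7 counted) did not pass the adjusted test. Counted tiles overlapped their closest feature in 42 cases, of which 25 were introns, 9 CpG islands and 8 exons or coding sequence. No class differed between negative and positive counted tiles (Fisher's exact tests, lowest adjusted p = 0.165). With overlapping tiles joined into 1193 loci, distal intergenic (odds ratio 5.73, Fisher's exact test, adjusted p = 1.17e-08), downstream (odds ratio 0.320, adjusted p = 0.0155) and 3′ UTR (odds ratio 5.15, adjusted p = 0.0140) passed. The within class did not, at an odds ratio of 0.466 as loci (Fisher's exact test, adjusted p = 0.0518) and 0.668 without the 6 blocks (adjusted p = 0.350). Exons moved to an odds ratio of 0.978 as loci (Fisher's exact test, adjusted p = 1) and 1.34 without the 6 blocks (adjusted p = 0.485).

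Chromosomes 14, 6 and X held more counted tiles than the rest, and 4 of the 6 blocks with the most counted tiles lay on them. Without those 6 blocks the odds ratio was 0 for chromosome 14, 0.955 for chromosome X (both adjusted p = 1) and 2.40 for chromosome 6 (Fisher's exact tests, adjusted p = 0.333). With all blocks, chromosome 14 had 49 of 515 listed tiles counted (9.51%, odds ratio 4.52, adjusted p = 1.69e-13), chromosome X, single in males, 49 of 710 (6.90%, odds ratio 3.09, adjusted p = 2.27e-08) and chromosome 6, 27 of 278 (9.71%, odds ratio 4.18, adjusted p = 9.42e-08; Fisher's exact tests). All counted tiles on these 3 chromosomes were negative. Of 12 chromosomes with no counted tile, chromosomes 2, 3, 4, 7, 10, 13 and 29 also passed the test, the largest of them being chromosome 13 with 519 listed tiles (Fisher's exact test, adjusted p = 3.23e-06). On chromosome 1 the signs were split, with 10 positive and 7 negative counted tiles, and the difference in sign from other chromosomes had an adjusted p of 2.14e-10 (Fisher's exact test). All 10 positive tiles lay in 1 block, and as loci the split was 3 positive and 2 negative (Fisher's exact test, adjusted p = 0.0423). Counted as loci, chromosome 14 (9 of 46, odds ratio 5.96, Fisher's exact test, adjusted p = 0.00165) and chromosome X (14 of 83, odds ratio 5.43, adjusted p = 0.000191) passed. Chromosome 6 (6 of 45, odds ratio 3.53, Fisher's exact test, adjusted p = 0.121) and the 7 chromosomes that had passed with no counted tile did not.

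Counted tiles lay close to one another. Of the 57 regions, 13 held a single tile, and the longest held 14 tiles. There were 342 pairs of counted tiles of one sign within 1000 bp, against a mean of 48.9 in permutations within chromosomes (permutation p = 1e-05, the smallest that the permutations can give). Overlapping tiles hold the same cytosines, so this test does not separate runs from overlap. Among pairs that share no base, an alternative chosen after seeing the data, there were 53 against a mean of 20.9 and a highest value of 57 in permutations (permutation p = 2e-05). Such pairs are not independent either, because each tile can bring overlapping counted neighbours that the permutations move singly. That p may therefore be too small. Blocks with many counted tiles accounted for most of the count, with 142 of the 203 tiles in 6 blocks. The block on chromosome X from 123863501 to 124075800 held 45 counted tiles of 326 listed, and 90.2% of its listed tiles were negative. Adjacent blocks on chromosome 14 held 23 counted tiles of 152 listed (13520201 to 13641900) and 26 of 296 (13754401 to 13839000). On chromosome 6, from 5433701 to 5459700, 23 of 116 tiles were counted and every listed tile was negative, with a mean difference of -6.60 percentage points. The blocks on chromosome 21 (32905601 to 33029400) and chromosome 1 (210901 to 474000) held 15 of 248 and 10 of 540. Of their listed tiles, 154 and 442 were negative.

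The genes with the most counted tiles were without a descriptive name in the table and are reported as uncertain. LOC784741 on chromosome X was the closest gene of 27 counted tiles out of 152 listed. Its largest value in the authors' deposited table was -16.1 percentage points (q = 1.18e-33) from 123948101 to 123948600, 36769 bp from a 3′ UTR. On chromosome 14, ENSBTAG00000052622 had 21 counted tiles of 124, and an intronic tile from 13777101 to 13777600 had -15.1 percentage points in the authors' deposited table (q = 1.30e-48). LOC618600 on chromosome X had 12 of 91, with -16.7 percentage points in the authors' deposited table (q = 4.77e-33) from 124021501 to 124022000, 17139 bp from a 5′ UTR. ENSBTAG00000006648 had 10 of 351 and ENSBTAG00000051816 on chromosome 18 had 6 of 111, while another unnamed gene on chromosome X also had 6, of 83. ENSBTAG00000051816 reached -15.0 percentage points in the authors' deposited table (q = 7.28e-31) at a promoter-classed tile from 57249301 to 57249800, 5598 bp from its coding sequence.

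**Figure D2:**
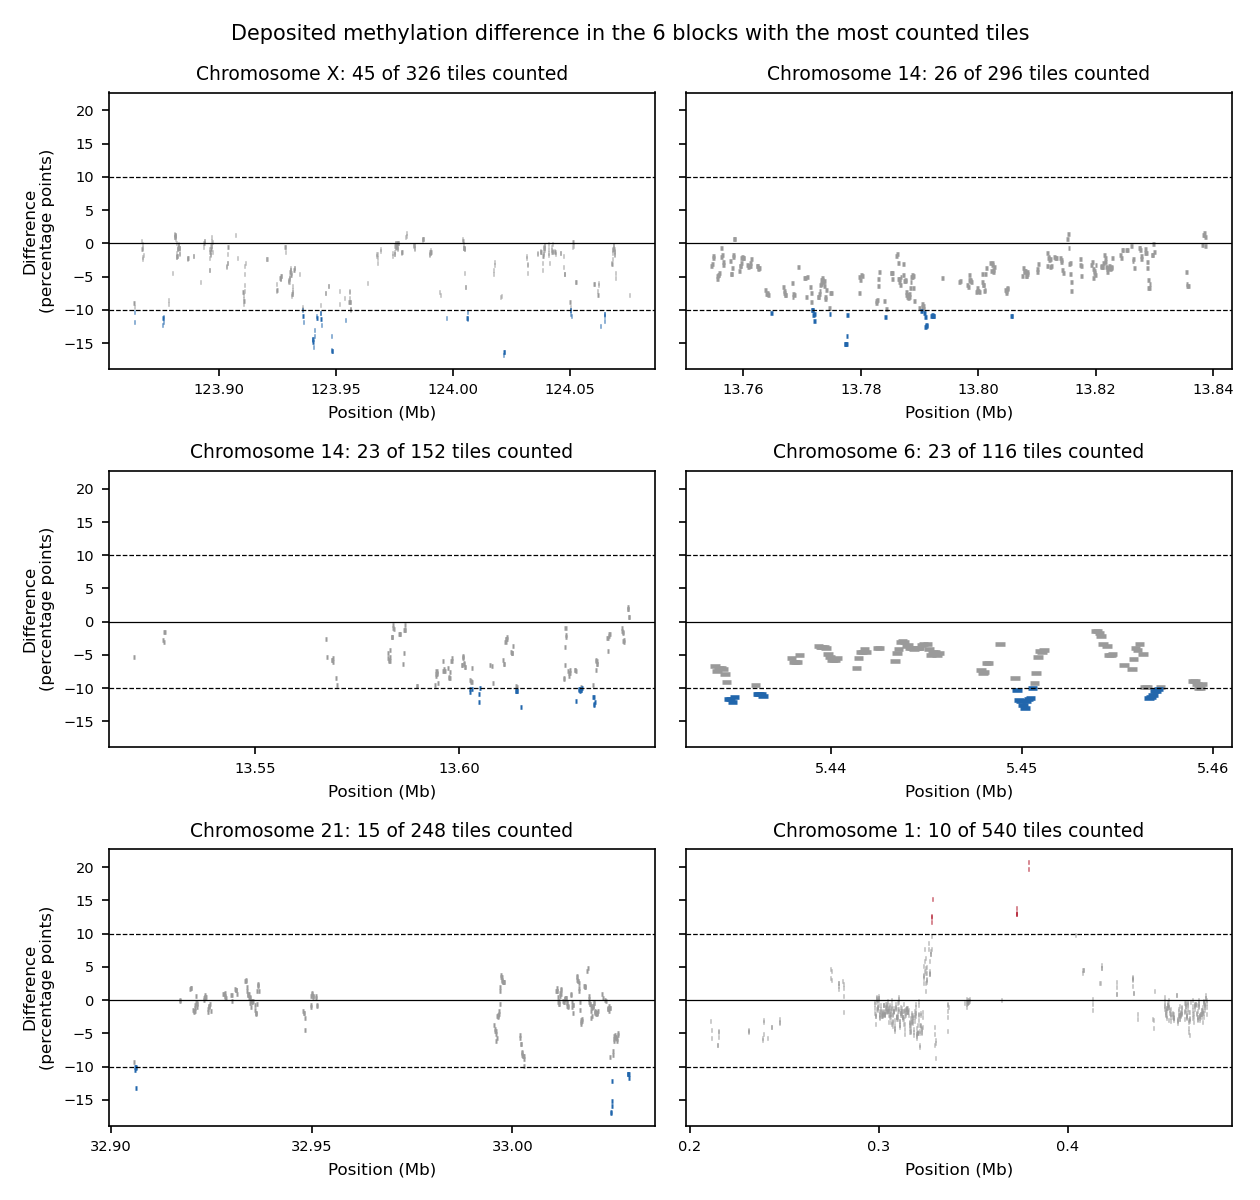
Deposited methylation difference in percentage points (vertical axis) by position in Mb (horizontal axis) in the 6 blocks with the most counted tiles, each bar 1 tile of 500 bp. Blue and red bars are counted negative and positive tiles, grey bars other listed tiles, and dashed lines mark 10 percentage points in either direction. Counted tiles sit within longer runs of smaller negative values on chromosomes X, 14 and 6. The counted tiles of the chromosome 1 block are all positive, although 442 of its 540 listed tiles are negative.

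No member of the 10 gene lists other than multicopy families had a counted tile, and the members named from these lists were chosen after their values were seen. These lists had 24 genes in the table, of which 16 had a tile with a q under 0.05 at any difference, against 396 of all 540 genes in the table. A counted tile was found for only 19 of all 540 genes, so its absence among 24 does not set these lists apart. None of these 10 lists passed the test against other genes at any difference. Lists with 1 or 2 genes in the table, and the epithelial and accessory gland list with 0, were too small to pass. For them this outcome was fixed in advance. Among imprinted genes, both listed members passed that q with negative differences, and both passed when adjusted over the list alone. PEG10, a paternally expressed gene derived from a retrotransposon, had -6.28 percentage points (q = 1.10e-10) in its 3′ UTR on chromosome 4, from 12072001 to 12072500, in the authors' deposited table. ZNF597 had -0.378 (q = 0.00303) in the authors' deposited table. The germline and sperm lists had 1 gene each. SPATA22, required for meiotic recombination, had 1.03 percentage points (q = 0.000509), and DPY19L2, required for sperm head formation, had -0.433 (q = 0.00236), both in the authors' deposited table. Both also passed when adjusted over the list alone, which adds little because each list held 1 gene.

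Developmental transcription factors had 8 listed genes, all with differences under 2 percentage points. HOXA2, TBX5, TBX2 and ZIC1 passed the q with negative differences, and 3 genes of the list passed when adjusted over the list alone. In the authors' deposited table HOXA2 had -1.04 percentage points (q = 0.00174) and TBX2 -0.816 (q = 8.62e-05), while LHX8, OTX2, EN1 and NKX2-1 did not pass. Of 2 chromatin regulators, TET2, which oxidises 5-methylcytosine, had a tile under that q and SMARCA2 had none, and 0 passed when adjusted over the list alone. For TET2 the largest value in the authors' deposited table was 1.65 percentage points (q = 0.0129). The deposited p of that tile was 0.0746, so it passed only because its q lay below its p. FZD3, a Wnt receptor, was the only gene in the table that matched the prefixes of the Wnt list, and CXXC4 matched none of them. FZD3 had -1.78 percentage points (q = 3.46e-05) in the authors' deposited table and passed when adjusted over its list of 1 gene. Of 4 calcium and cAMP genes, ADCY9 alone passed, at -0.459 (q = 0.00392) in the authors' deposited table, and 0 did so when adjusted over the list alone. All 4 synapse genes passed either way, GRIK1 and GABRB1 with positive and CSMD3 and DLGAP1 with negative differences. CSMD3 reached -5.92 percentage points (q = 5.87e-14) in an intron on chromosome 14, in the authors' deposited table.

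Among markers of other cells of the ejaculate, the leukocyte list had 1 gene in the table and the epithelial and accessory gland list 0. The leukocyte gene IKZF1, a lymphoid transcription factor, had 4.97 percentage points (q = 3.25e-06) in an intron on chromosome 4 in the authors' deposited table, and passed when adjusted over its list of 1 gene. Multicopy families and nameless IDs were counted more often than other genes, 10 of 120 against 9 of 420 (odds ratio 4.15, Fisher's exact test, p = 0.00307, adjusted p = 0.0337). All 10 were also counted when adjusted over the list alone. With genes matched on their number of listed tiles the mean of the permutations was 11.6 and the permutation p was 0.522, and with genes limited to features within 5000 bp the adjusted p was 0.207.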

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

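The alternatives with p in place of q, a minimum of 5 percentage points, non-overlapping tiles, unshared bases and the omission of the 6 blocks with the most counted tiles were chosen after seeing the data. The 203 counted tiles stayed 203 at q under 0.01, at q under 0.001, with Bonferroni or Benjamini-Hochberg adjustment over the listed tiles and with p under 0.05 in place of q. The highest deposited q and p of a counted tile were 1.18e-11 and 9.76e-12. These settings therefore could not remove any counted tile, and the unchanged count is no support for it. On autosomes alone the count came to 154. The count followed the minimum difference, at 5236 tiles with none, 1124 at 5 percentage points, 8 at 20 and 0 at 25 with q under 0.01, since the largest listed difference is -21.3. It was 50 among non-overlapping tiles and 57 as merged regions, which count overlapping tiles once, and 61 without the 6 blocks, which held the other 142. The negative share stayed past its threshold at 77.8% to 98.4%, except with the 20-point minimum (87.5%), where 8 tiles remain. Of 10 classes and types, 5 passed in the reported setting, against 6 with no minimum difference, 4 without the 6 blocks, 3 as merged loci, 1 at 20 percentage points and 1 for within against outside, where only that contrast is tested. Without the 6 blocks distal intergenic (odds ratio 2.33) and downstream (0.356) kept their side, the within class, exons and 3′ UTRs did not, and coding sequence (odds ratio 2.11, Fisher's exact test, adjusted p = 0.0262) and CpG islands (0.334, adjusted p = 0.00226) passed. The class that passed at 20 percentage points was coding sequence. With no minimum difference 3′ UTRs (odds ratio 1.37, Fisher's exact test, adjusted p = 0.0835) and exons (1.02, adjusted p = 0.791) missed the threshold, and CpG islands (0.848), 5′ UTRs (0.752) and introns (1.24) passed. Of 27 chromosomes, 10 passed, against 1 at 20 percentage points, 20 with no minimum difference, 2 as merged loci (14 and X) and 2 without the 6 blocks. Those without the 6 blocks were chromosomes 1 (odds ratio 3.98, Fisher's exact test, adjusted p = 0.0451) and 15 (5.02, adjusted p = 0.00137), and chromosome 15 was also the one at 20 percentage points, none of them among the 10. With no minimum difference chromosome 13 turned from no counted tile to an odds ratio of 1.48 (Fisher's exact test, adjusted p = 0.000449), and the cause was not tested. The single gene list that passed became 0 at 20 percentage points, 0 with features within 5000 bp and 0 when matched on listed tiles. Clustering kept its side of the threshold at 500 and 5000 bp, where overlap of tiles contributes, and among pairs that share no base, which are still not independent. All 17 named tiles kept their side under the stricter q and both adjustments, which could remove no counted tile, and 3 did at 20 percentage points. Merging was not run for gene lists, which are already per gene. Coverage minimums, samples left out in turn and a model on transformed fractions were not run, and other splits of the samples were not drawn, because values per sample were not used here. No paired analysis was possible because the groups share no sample numbers and the comparison is the authors' own. Without values and depth per sample, the spread between bulls behind each difference is unknown.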

Other observations

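All tests in this part were chosen after the values were seen. Below the 10-point minimum, 20 further genes with a description in the table had a tile with a q under 0.05 and a difference of 5 to 10 percentage points in or within 5000 bp of an annotated feature, 16 of them negative. In the authors' deposited table, introns of SPATA1, named as a spermatogenesis-associated gene, and of HRH2, a histamine receptor, had -9.69 and -9.61 percentage points (q = 2.87e-27 and 9.06e-42). The sorting receptor SORCS3 had -8.02 in the authors' deposited table, the deubiquitinase OTUD7A -7.92, the G protein subunit GNAQ -7.79 and the vesicle fusion gene VAMP7 on chromosome X -6.81, also in introns. The authors' deposited table lists positive values for the coding sequence of the cannabinoid receptor CNR1 (5.13 percentage points, q = 4.38e-08) and for the 5′ UTR of a glycine-N-acyltransferase-like gene on chromosome 15 (7.21), near GLYAT with its negative tile.

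The negative sign was also the commoner one outside the counted tiles. Of the 1193 loci, 61.8% had a negative largest difference (95% exact interval 59.0% to 64.5%, exact binomial p = 3.83e-16), and of 509 loci in blocks of at most 3 tiles 56.2% did (exact binomial p = 0.00594). Loci also share the same samples, so these p-values do not measure the spread between samples. Tiles with a q under 0.05 and 5 to 10 percentage points were negative in 850 of 921 cases, and those under 1 percentage point in 633 of 1139.

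For the predominance of negative counted tiles, incomplete conversion of unmethylated cytosines in one group would shift CpG islands and 5′ UTRs, which are mostly unmethylated in sperm, yet the 1323 tiles overlapping them had a median difference of -0.106 percentage points (5th to 95th percentile -3.23 to 1.22). Mostly unmethylated tiles cannot show whether methylated cytosines were wrongly converted in one group, and that was not tested. The other listed tiles had a median of -1.45 percentage points. A few blocks do not carry the predominance of negative tiles, since 95.8% of the 24 counted regions outside the 6 blocks with the most counted tiles were negative (23 regions). Somatic cells in the samples of one group may contribute and cannot be told apart here, because the germline and sperm lists had 2 genes in the table, with a median of 0.298 percentage points. A biological difference between the low BFI and high BFI groups stays open and untested.

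A p of 0 was listed for 27 tiles, of which 0 reached 10 percentage points. In the authors' deposited table they were 8 tiles on chromosome 2 from 121572201 to 121573600, at 1.47 to 3.25 percentage points, and 19 on chromosome 21 between 33002101 and 33026500, at -9.86 to -5.25, inside the block on that chromosome with 15 counted tiles.

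Values of q lay below p for 5007 tiles, and 441 tiles had a q under 0.05 with a p of 0.05 or more, up to a p of 0.503. Adjustment over the listed tiles of a chromosome cannot by itself put q below p. A further factor under 1 would be needed, and its origin was not tested. Within chromosomes q mostly followed the rank of p: q times rank over p was constant within 1% for 88.8% of tiles, and q never fell with rising p within a chromosome. The share was lower on chromosomes 16 (5.90%), 7 (28.6%), 15 (31.1%) and 3 (59.4%), where the cause was not tested. The median of q times rank over p, divided by the number of tiles listed on the chromosome, ran from 0.00488 on chromosome 28, where all 87 tiles had a q under 0.05, to 0.611 on chromosome 22. The highest p of a counted tile was 9.76e-12, so no counted tile rests on this. The largest TET2 difference does, with a deposited p of 0.0746 and a q of 0.0129. No biological explanation was tested for this pattern.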
